A study of Homo sapiens with 6 samples.

How the data were processed

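Gene expression was measured in human umbilical vein endothelial cells (HUVECs) transfected with a small interfering RNA (siRNA) against the long noncoding RNA ANRIL or with a scrambled control siRNA, with 3 Affymetrix Human Genome U133 Plus 2.0 arrays per group, 1 array per transfected sample. The deposited table holds log2 values for 54675 probe sets on 6 arrays. Per the submitters' processing notes, RMA, the affy package and limma were used. Their versions, and whether any probe set was filtered, are not given in the sources used here. RMA corrects background, applies quantile normalization across arrays and summarises the probes of each probe set on the log2 scale. Since the normalization comes before the summary, the deposited columns need not be identical in distribution, and their medians lay between 6.14 and 6.23. Where quantile normalization was repeated here, it was applied to the probe set values.

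From these log2 values, 62 control probe sets were left out and 54613 were tested. Gene names came from the platform annotation supplied with the series, which can be old, and symbols were updated through Entrez identifiers in the RefSeq gene table of GRCh38.p14. Of the tested probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 were not listed, and no gene was named from a probe set with several. Of those with 1 symbol, 41037 matched the RefSeq table. No genome build is named for the values, so no coordinates are given. For gene-level tests each of 19777 genes was represented by its probe set with the highest mean over all 6 arrays.

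Differences are ANRIL siRNA minus control siRNA on the log2 scale, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with a constant prior. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. All adjusted p-values are two-sided. The replicate number was not used in this fit. For gene lists, camera of limma was run with a preset correlation between genes of 0.01 and adjusted over the 25 lists tested. Camera with an estimated correlation and fry were alternatives. Members were also tested with p adjusted over the list alone. Each list's median was set against 10000 random lists of the same size matched on mean expression. Their genes were drawn separately, so these lists lack the correlation between members of a real list.

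The grouping of samples, the tests, the gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. The rule took, per direction, up to 15 genes passing the threshold, above the median signal and with no overlap between the groups. Where fewer than 10 qualified, it filled up to 10 with the genes of smallest p that met the other conditions, and such genes are named as not passing. It also took ANRIL, its neighbours CDKN2A, CDKN2B and MTAP, the study's follow-up genes CLIP1, EZR and LYVE1, and the 4 members of smallest p in each list. The study is known to have followed up CLIP1, EZR and LYVE1 after seeing these arrays.

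The alternatives chosen in advance were the replicate number as a block, array weights, an intensity-trended robust prior, repeated quantile normalization, centring on array medians, a filter at the median signal, other thresholds, other rules for probe sets of a gene, other list tests, and each array left out in turn. Cyclic loess normalization, an intensity trend without the robust option, and their combinations were added after the data had been seen. The same holds for leaving out each array with the trended robust prior, and for counts and calls of list members under other settings. Exact permutation tests were used for single values.

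The fit was tested on simulated data with 54613 probe sets and 3 against 3 arrays. It recovered 77% of probe sets changed by 1.5-fold and 98% of those changed by 2-fold, with 4 false calls. Camera called the 1 list of 25 that had been shifted by −0.15. The simulated genes varied independently of each other and without a trend with signal. The simulation therefore does not check the preset correlation or the effect of an intensity trend.

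The precision is limited by the number of arrays. The labels give 3 sets of cells and do not say whether they came from separate cultures or donors, so p-values measure the spread between these samples, which may be technical. The residual SD of a probe set was highest among dim probe sets, with a median of 0.115 in decile 3 of mean signal and 0.059 in decile 10, the brightest.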

Results

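Expression was profiled in HUVECs, primary endothelial cells from the vein of the umbilical cord, after transfection with an siRNA against ANRIL or with a scrambled control siRNA. ANRIL, listed as CDKN2B-AS1, is a long noncoding RNA transcribed from the CDKN2A and CDKN2B locus on chromosome 9p21, a region known for its association with coronary artery disease. Each group had 3 arrays, and the single comparison of the design asked which genes lie downstream of ANRIL. Pairs of arrays correlated at r = 0.9971 to 0.9977 within groups and at 0.9964 to 0.9974 between groups, across probe sets, which are not independent replicates. The values were RMA log2 intensities as deposited, with array medians of 6.14 to 6.23, and the number of arrays limits the precision of all differences given here.

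The targeted transcript was read by 1 probe set, which lay near the floor of the array, with a mean at percentile 9.4 of all probe sets. Its log2 values were 4.08, 4.05 and 3.95 with control siRNA and 3.69, 4.05 and 4.05 with ANRIL siRNA. The difference was −0.10 ± 0.10 (SE, n = 3 per group, 95% interval −0.32 to 0.13, limma adjusted p = 0.666). Without ANRIL siRNA replicate 1 it was 0.02, so the sign rested on that array. The array therefore gave no check of the knockdown at this signal. Which ANRIL transcripts the probe set reads was not analysed here. Among the 9p21 neighbours, CDKN2A, which encodes p16 and p14ARF, differed by −0.15 ± 0.06 at its brightest probe set and by −0.20 ± 0.08 at the next (adjusted p = 0.321 and 0.28). The brightest probe set of CDKN2B differed by −0.10 ± 0.07 and that of MTAP by −0.06 ± 0.07, and MTAP turned to 0.00 after repeated quantile normalization. Of the 6 MTAP probe sets 4 were lower, and that of rank 3 in mean signal differed by 0.25 ± 0.09 (adjusted p = 0.261). None of these passed. All 4 members of the list of 9p21 neighbours, with DMRTA1 at −0.18 ± 0.09, were lower, and the list did not pass (median −0.12, adjusted p = 0.0559, and 0.466 with an estimated correlation). It passed with the replicate number as a block (0.0382), with the mean of all probe sets per gene (0.0345) and without probe sets ending in _s_at or _x_at (0.0386). Its median was −0.06 after cyclic loess (adjusted p = 0.119), and 1 of 4 members lay above 0 after repeated quantile normalization.

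Among genes above the median signal and with no overlap between the groups, those of smallest p were lower with ANRIL siRNA. They included several genes of endothelial cells. Bright probe sets in general tended lower, with 39.3%, 20.7% and 12.9% above 0 in deciles 8, 9 and 10 of mean signal. The lower direction is thus not particular to the genes named here. TIE1, an endothelial receptor tyrosine kinase, differed by −0.42 ± 0.06 (SE, n = 3 per group; control 11.27 ± 0.03, ANRIL siRNA 10.85 ± 0.06, mean ± SD). NRP2, a co-receptor for VEGF-C and semaphorins, differed by −0.44 ± 0.06, and LYVE1, a hyaluronan receptor of lymphatic endothelium, by −0.43 ± 0.07. TNFSF10, which encodes the death ligand TRAIL, was 1.55-fold lower (−0.63 ± 0.10) and all 3 of its probe sets were lower. For NRP2 8 of 11 probe sets were lower and their mean differed by −0.12, and for TIE1 both were lower, the dimmer by −0.13. TMEM100, a transmembrane protein of endothelium, was 1.63-fold higher (0.71 ± 0.13). None of these differences passed the threshold over all 19777 genes, where each had an adjusted p of 0.125.

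The limma fit with a constant prior called 0 of 54613 probe sets and 0 of 19777 genes, with smallest adjusted p-values of 0.201 and 0.125. At an unadjusted p under 0.05 it gave 4891 probe sets higher and 3355 lower, 8246 in all against 2731 expected by chance, and 1944 genes higher and 1613 lower against 989 expected. The 3 values of each group did not overlap at 21% of probe sets and 23.4% of genes, where chance gives 10%. These chance figures allow for no shift shared by many probe sets. Such a shift was present, with 69.3% of probe sets above 0 in decile 4 of mean signal and 12.9% in decile 10. With arrays of both siRNAs mixed in each group, an unadjusted p under 0.05 gave 1356 to 4775 probe sets and 415 to 2122 genes. The excess over chance therefore does not tell changes of single genes from a shared shift. With the planned intensity-trended robust prior, 29 probe sets rose and 315 fell, and 115 genes rose and 426 fell. With the constant prior and genes above the median signal only, 55 genes rose and 254 fell, and with arrays centred on their medians 1 rose and 31 fell. After cyclic loess, a scaling chosen after the data had been seen, the trended prior called 20 probe sets higher and 58 lower, and 59 genes higher and 75 lower. The trended counts also moved when an array was left out, from 2 genes higher and 37 lower without control replicate 2 to 352 higher and 1118 lower without ANRIL siRNA replicate 2. The median log2 difference was 0.01 over probe sets.

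Beside those above, the lower genes taken by the naming rule were DEPP1 (−0.49 ± 0.07), the cholesterol exporter ABCG1 (−0.58 ± 0.09), the stress-induced growth arrest gene GADD45A (−0.36 ± 0.06), the glutaminyl cyclase gene QPCT (−0.40 ± 0.06), RGCC (−0.43 ± 0.07) and RBM41 (−0.45 ± 0.07). Their adjusted p was 0.125 each. The other higher genes were CACNA2D2, a calcium channel subunit (0.36 ± 0.07), the histone methyltransferase gene SETMAR (0.32 ± 0.06), KREMEN2 (0.30 ± 0.06), TMPRSS5 (0.35 ± 0.08), CPXM2 (0.31 ± 0.07), the mucin MUC5AC (0.37 ± 0.08), PGLYRP4 (0.26 ± 0.06), the protease inhibitor SPINT1 (0.34 ± 0.08) and the urate transporter SLC2A9 (0.27 ± 0.06). Their adjusted p-values lay between 0.138 and 0.147. With the intensity-trended robust prior 19 of these 20 genes passed, all except PGLYRP4 (adjusted p = 0.0524), and after cyclic loess 15 passed with that prior. The 20 genes were picked by smallest p on the same arrays, so their passing is not independent evidence. Other probe sets of a gene did not always move alike. Only 1 of 3 SETMAR probe sets, 1 of 4 for MUC5AC, 1 of 2 for SPINT1 and 1 of 2 for RBM41 had the given sign. RGCC was lower at 1 of 3 probe sets and turned to 0.10 once probe sets ending in _s_at or _x_at were left out. SETMAR turned to −0.02 as the mean of its probe sets. Under that rule others shrank, to 0.012 for MUC5AC, 0.128 for CPXM2 and 0.165 for SPINT1. RBM41 was then at −0.215, ABCG1 at −0.273 and DEPP1 at −0.319.

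**Figure D1:**
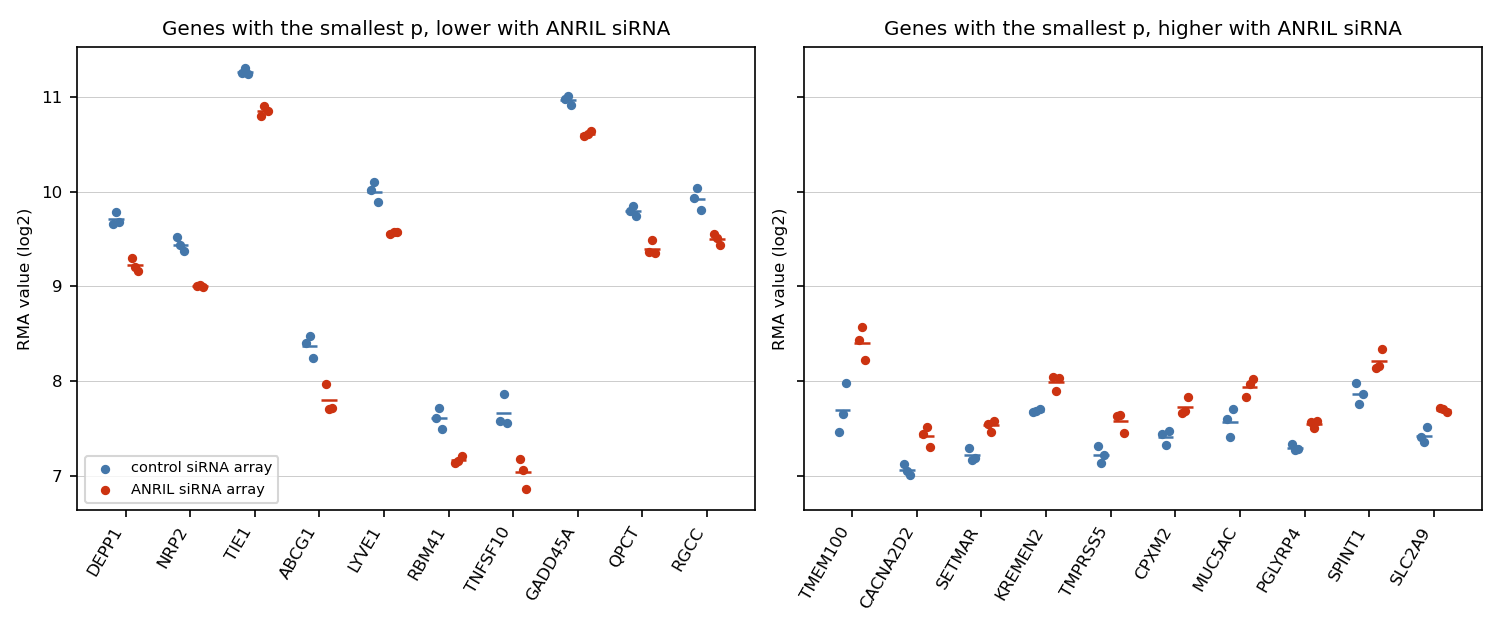
RMA log2 values of each array for the 20 genes taken by the naming rule, with control siRNA in blue, ANRIL siRNA in red and short lines at the group means. The groups do not overlap in any of these genes, which the rule required, and the largest difference is that of TMEM100 (0.71).

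The genes that the study followed up, LYVE1, EZR and CLIP1, were chosen on these samples and so are not independent evidence. LYVE1 was lower at both of its probe sets, by −0.43 ± 0.07 at the brighter and −0.56 ± 0.07 at the dimmer, and both passed when adjusted over the list alone, that is over the probe sets of these 3 genes (adjusted p = 0.000897 and 0.000175), but not over all probe sets (adjusted p = 0.22 for both). EZR encodes ezrin, which links membranes to actin, and CLIP1 encodes a microtubule plus-end protein. With probe sets ranked by mean signal from the brightest, EZR differed by −0.59 ± 0.21 at rank 4 of 5 (adjusted p = 0.267), while its brightest probe set differed by −0.05 ± 0.08 and turned to 0.03 after cyclic loess and 0.04 after repeated quantile normalization. Without _s_at and _x_at probe sets EZR was at 0.17. CLIP1 differed by −0.58 ± 0.24 at rank 5 of 6 (adjusted p = 0.307) and at its brightest probe set by −0.13 ± 0.08. At both dimmer probe sets control replicate 1 stood above the other controls, at 8.09 against 7.09 and 7.41 for EZR and 6.46 against 5.29 and 5.44 for CLIP1. Without that array the differences were −0.31 and −0.21.

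**Figure D2:**
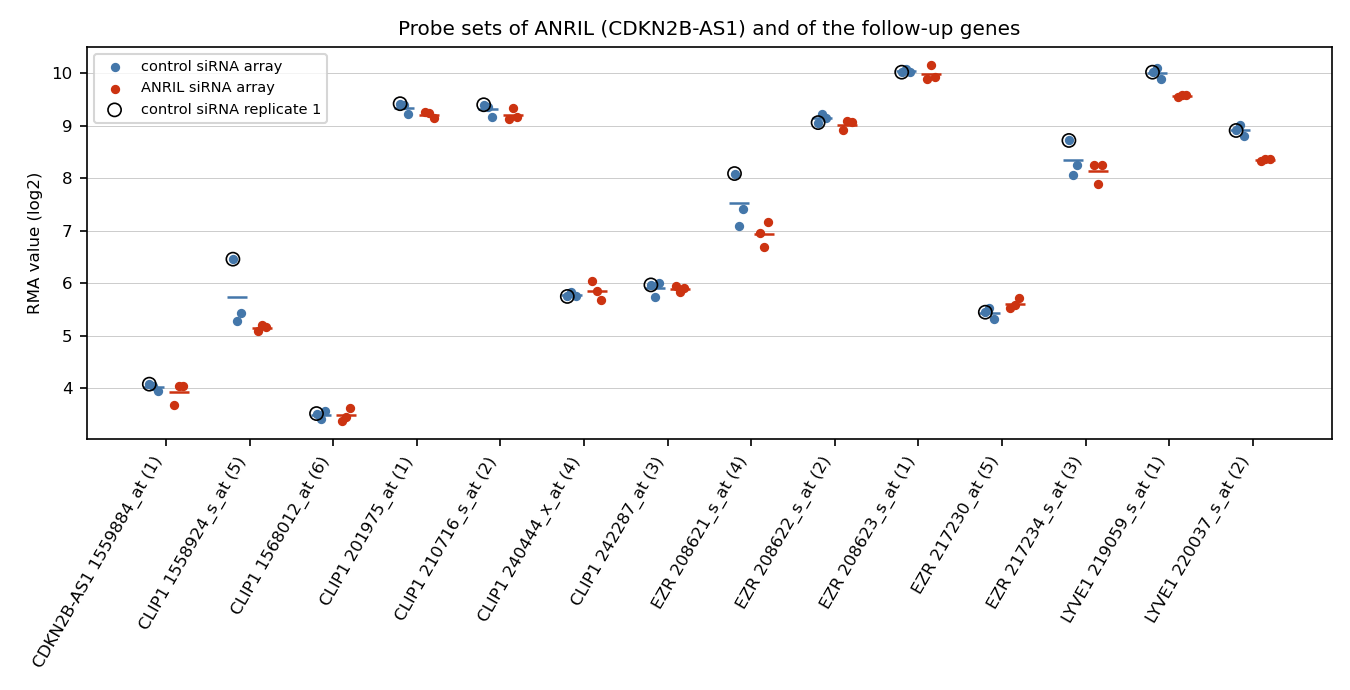
RMA log2 values of each array at the probe sets of ANRIL, CLIP1, EZR and LYVE1, with control siRNA in blue, ANRIL siRNA in red, lines at the group means and a ring around control replicate 1. The number in brackets is the rank by mean signal within the gene. LYVE1 is lower at both probe sets, while the ringed array lies above the other controls at EZR rank 4 (8.09) and CLIP1 rank 5 (6.46).

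Of the 25 gene lists, 11 were lower and 1 higher by camera with the preset correlation. Of the 11, 1 is the list that the study chose on these samples, which is not independent evidence. LYVE1 is also a member of the endothelial identity and lymphatic lists, and EZR and CLIP1 are members of the adhesion and actin list. Those lists are thus not wholly independent of the study's choice. With an estimated correlation 0 passed, and with fry 1 passed, the lymphatic list (adjusted p = 0.0276). No member of any list passed over all genes. Bright probe sets tended to be lower with ANRIL siRNA (median −0.08 in the brightest decile) and dim ones higher (0.06 in the decile 4). The calls of the endothelial identity, p53 and interferon lists, 3 of the 12, were also made after repeated quantile normalization and after cyclic loess, which removes that trend. The signal of ACTB probe sets at the 3' end exceeded that at the 5' end by 0.72 ± 0.13 (SD) with ANRIL siRNA and 0.54 ± 0.05 with control siRNA (n = 3 per group, two-sided exact permutation p = 0.2, where 0.1 is the smallest p possible), and the same difference for GAPDH was higher by 0.06 (exact permutation p = 0.1).

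The list of endothelial identity was lower, with 25 of 26 measured members below 0 and a median of −0.17 (adjusted p = 5.96e-10). With an estimated correlation the adjusted p was 0.466, and with fry 0.0591. Random lists of like expression were lower too, with a median of −0.07. Adjusted over the list alone, 14 members fell. They were led by TIE1, LYVE1, CLDN5 (−0.34 ± 0.06), a tight-junction protein, and ICAM2 (−0.29 ± 0.06), an adhesion molecule, and included the junction genes CDH5 (−0.28 ± 0.07) and PECAM1 (−0.16 ± 0.06), of which PECAM1 lost its call after cyclic loess and repeated quantile normalization and CDH5 did not. That count was 10 without control replicate 1, 4 without control replicate 2, 6 without ANRIL siRNA replicate 1 and 8 without ANRIL siRNA replicate 3, and 5 after cyclic loess or repeated quantile normalization. After cyclic loess the list remained lower (21 of 26 members below 0, median −0.10, adjusted p = 4.59e-06, or 0.122 with an estimated correlation), below every one of 10000 random lists of like expression. After repeated quantile normalization 19 of 26 members lay below 0. Of the lists of other cells, leukocyte markers were higher (8 of 10 members above 0, median 0.14, adjusted p = 0.034, and 0.466 with an estimated correlation). CD3E (0.22 ± 0.08), CD3D (0.19 ± 0.08), MS4A1 (0.18 ± 0.08, but −0.12 without _s_at and _x_at probe sets) and ITGAM (0.22 ± 0.10) were dim and none passed over the list alone. The call ended after cyclic loess (adjusted p = 0.36), without _s_at and _x_at probe sets (0.206), without control replicate 1 (0.0508) and without ANRIL siRNA replicate 3 (0.225). Smooth muscle markers (median 0.05, adjusted p = 0.356) included ACTA2, which fell when adjusted over the list alone (−0.26 ± 0.06, but without a call after cyclic loess or repeated quantile normalization), and CSPG4, LMOD1 and NOTCH3 at 0.17 to 0.20. Fibroblast markers had a median of −0.02 and a mean of 0.01 (adjusted p = 0.919), with MFAP5 at 0.26, COL3A1 at −0.18 (0.18 without _s_at and _x_at probe sets), COL1A1 at 0.15 and OGN at 0.15, and 1 member was lower over the list alone after cyclic loess and after repeated quantile normalization. Epithelial markers had a median of −0.02 (adjusted p = 0.836), and adjusted over the list alone ESRP1 rose (0.30 ± 0.08, but −0.06 once probe sets ending in _s_at or _x_at were left out) while the keratins KRT18 (−0.20 ± 0.06) and KRT19 (−0.23 ± 0.07) fell. None of these 3 calls was made after cyclic loess or repeated quantile normalization.

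Lymphatic endothelial markers were lower at 6 of 10 members and did not pass (median −0.08, adjusted p = 0.0559), but passed after cyclic loess (median −0.09, adjusted p = 0.0261, or 0.305 with an estimated correlation). NRP2 and LYVE1 fell when adjusted over the list alone, while TFF3 (0.12 ± 0.06) and MMRN1 (−0.16 ± 0.08) did not pass. Both NRP2 and LYVE1 are in other lists too. The list of angiogenic and Notch signalling was lower (22 of 29 members, median −0.10, adjusted p = 0.00465, and 0.466 with an estimated correlation). NRP2, the chemokine receptor CXCR4 (−0.52 ± 0.12) and NRP1 (−0.27 ± 0.07) fell when adjusted over the list alone, and HES1 (−0.23 ± 0.07, but 0.13 without _s_at and _x_at probe sets) did not pass. Of these member calls only that of NRP2 was made after cyclic loess and repeated quantile normalization. The list's call ended after cyclic loess (adjusted p = 0.323) and repeated quantile normalization (0.347). Flow-responsive genes did not pass as a list (11 of 16 lower, median −0.04, adjusted p = 0.063), although adjusted over the list alone 5 members fell, among them TXNIP (−0.26 ± 0.06), the caveolar protein CAV1 (−0.25 ± 0.07) and KLF6 (−0.22 ± 0.07), and the heme oxygenase gene HMOX1 rose (0.28 ± 0.09). All 5 falls lost their call after cyclic loess and repeated quantile normalization, while that of HMOX1 was made after both, and the list's median turned to 0.01 after cyclic loess.

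Targets of p53 were lower, at 25 of 27 members (median −0.14, adjusted p = 2.47e-07, and 0.466 with an estimated correlation). Random lists of like expression were lower too, with a median of −0.06. Adjusted over the list alone 5 members fell: GADD45A, the p53 ubiquitin ligase gene MDM2 (−0.30 ± 0.06), the DNA repair gene DDB2 (−0.26 ± 0.07), the TRAIL receptor gene TNFRSF10B (−0.23 ± 0.06) and SPATA18. That count was 2 without control replicate 2, without ANRIL siRNA replicate 1, without ANRIL siRNA replicate 3 or with the mean of all probe sets per gene. It was 1 after repeated quantile normalization and 3 after cyclic loess, and 10 above the median signal only, 11 with arrays centred on their medians, 12 with an intensity trend alone and 13 with the intensity-trended robust prior. The list remained lower after cyclic loess (23 of 27 members below 0, median −0.07, adjusted p = 0.000173, or 0.122 with an estimated correlation). The interferon response list was lower at 25 of 33 members (median −0.12, adjusted p = 0.0039, and 0.516 with an estimated correlation), and the call ended without ANRIL siRNA replicate 2 (adjusted p = 0.123). Adjusted over the list alone, the chemokine gene CXCL11 (−0.82 ± 0.16) and the helicase gene DDX60 (−0.36 ± 0.08) fell, the antiviral GTPase gene MX2 rose (0.37 ± 0.10, with the call ending after cyclic loess and repeated quantile normalization), and IFI27 (−0.18 ± 0.06) did not pass. After cyclic loess the list was lower (median −0.10, adjusted p = 0.000141, or 0.395 with an estimated correlation). The list of NF-kB inflammatory genes did not pass (median 0.01, mean −0.03, adjusted p = 0.42). Its member CCL2, a monocyte chemokine, fell when adjusted over the list alone (−0.42 ± 0.08), and ICAM1 (−0.23 ± 0.08), NFKB1 (−0.15 ± 0.06) and VCAM1 (−0.15 ± 0.06) did not pass.

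Several lists of bright genes were lower in the deposited values and no longer passed after cyclic loess. Adhesion and actin genes were lower at 32 of 36 members (median −0.08, adjusted p = 0.000197, and 0.466 with an estimated correlation), with ITGA3 (−0.20 ± 0.06), ITGA2 (−0.21 ± 0.07), RHOJ (−0.17 ± 0.06) and PFN1 (−0.19 ± 0.07), and their adjusted p after cyclic loess was 0.384. Basement membrane and matrix genes were lower at 24 of 28 members (median −0.10, adjusted p = 0.000322, and 0.466 with an estimated correlation), with NID1 (−0.24 ± 0.08), FBN1 (−0.19 ± 0.06) and LAMB1 (−0.22 ± 0.07), while the metalloproteinase inhibitor TIMP3 rose when adjusted over the list alone (0.27 ± 0.06). The list's adjusted p after cyclic loess was 0.323. Oxidative phosphorylation genes were lower at 34 of 36 members (median −0.05, adjusted p = 0.0027, and 0.603 with an estimated correlation), but their median lay at percentile 85.7 of random lists of like brightness, whose own median was −0.07. The members of smallest p were UQCRC1 (−0.22 ± 0.07), COX5A (−0.16 ± 0.06), ATP5PB (−0.15 ± 0.06) and UQCRC2 (−0.13 ± 0.06), of which COX5A turned to 0.03 and ATP5PB to 0.11 without _s_at and _x_at probe sets, where the list's call ended (0.206). The list's median turned to 0.02 after cyclic loess and repeated quantile normalization. Genes of the RNA interference machinery were lower at 11 of 12 members (median −0.09, adjusted p = 0.00465, and 0.466 with an estimated correlation), with DICER1 (−0.20 ± 0.06), PRKRA (−0.22 ± 0.08), TNRC6B (−0.18 ± 0.08) and AGO3 (−0.13 ± 0.07). DICER1 turned to 0.05 as the mean of its probe sets, and the list's call ended under that rule (adjusted p = 0.0887) and after cyclic loess (0.119). The medians of the adhesion, matrix and RNA interference lists lay at percentiles 9.9, 0.7 and 13.9 of such random lists. In that order they lay at 18.8, 0.55 and 19.7 after cyclic loess and at 0.7, 0.14 and 20.6 after repeated quantile normalization. For the adhesion list the percentile thus depended on the scaling.

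Hypoxia and glycolysis genes were lower at 21 of 28 members (median −0.04, adjusted p = 0.0151, and 0.603 with an estimated correlation), and their median lay at percentile 83.8 of random lists of like brightness and turned to 0.02 after cyclic loess. ANGPTL4 fell when adjusted over the list alone (−0.29 ± 0.06, with the call ending after cyclic loess and repeated quantile normalization), and PFKFB3 (−0.21 ± 0.06), PKM (−0.21 ± 0.07) and BNIP3L (−0.18 ± 0.06) did not pass. Polycomb components were lower at 16 of 21 members (median −0.07, adjusted p = 0.0348, and 0.601 with an estimated correlation), with PCGF1 at 0.26 ± 0.08, the methyltransferase gene EZH2 at −0.15 ± 0.06, RBBP4 at −0.13 ± 0.06 (0.01 without _s_at and _x_at probe sets) and RBBP7 at −0.12 ± 0.06. That call ended without any of 5 arrays, with adjusted p-values of 0.133 without control replicate 2, 0.0553 without control replicate 3, and 0.0522, 0.0571 and 0.0589 without ANRIL siRNA replicates 1, 2 and 3, and it ended after cyclic loess (0.721) and without _s_at and _x_at probe sets (0.257). The list of LYVE1, CLIP1 and EZR, chosen by the study on these samples, was lower (median −0.13, adjusted p = 0.0287, and 0.466 with an estimated correlation), and the call ended without control replicate 1 (0.0687), without ANRIL siRNA replicate 1 (0.0961), without ANRIL siRNA replicate 3 (0.0518) and after cyclic loess (0.132).

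Genes of S phase did not pass (23 of 35 lower, median −0.04, adjusted p = 0.275), with TYMS at −0.21 ± 0.06, MCM7 at −0.23 ± 0.07, SLBP at −0.14 ± 0.06 and MCM10 at 0.22 ± 0.09. Mitotic genes did not pass either (24 of 38 higher, median 0.03, adjusted p = 0.541, turning lower in the test after cyclic loess and repeated quantile normalization), with KIF23 at −0.25 ± 0.07, HMMR at 0.21 ± 0.07, ASPM at −0.21 ± 0.07 and CCNB1 at −0.17 ± 0.06, which turned to 0.13 without _s_at and _x_at probe sets. TGF-beta and mesenchymal genes had a median of −0.01 (adjusted p = 0.417), which turned to 0.04 after cyclic loess, with TGFBR2 at −0.22 ± 0.06, TAGLN at −0.22 ± 0.07, SMAD6 at 0.24 ± 0.08 and TGFB1 at −0.20 ± 0.07, of which TAGLN turned to 0.18, SMAD6 to −0.03 and TGFB1 to 0.08 without _s_at and _x_at probe sets.

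**Figure D3:**
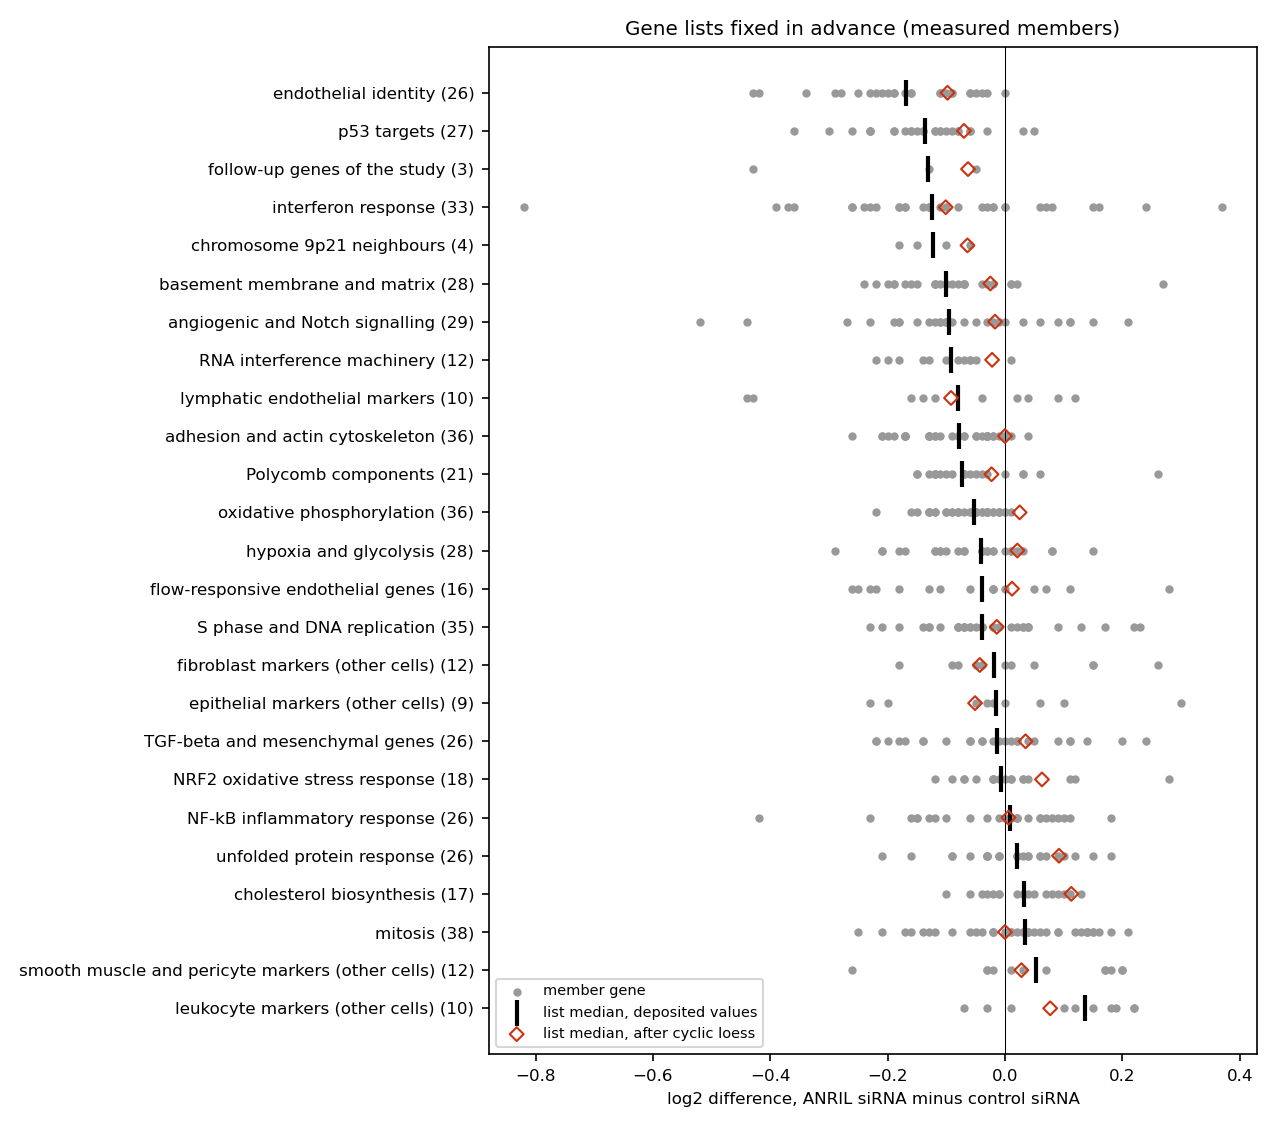
Log2 difference (ANRIL siRNA minus control siRNA) of each measured member of the 25 gene lists as grey points, with the list median in the deposited values as a black bar and after cyclic loess as a red diamond. The endothelial identity median lies at −0.17 and moves to −0.10, and that of oxidative phosphorylation moves from −0.05 to 0.02.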

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

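The comparisons in this part were chosen after the values had been seen. They concern control probe sets of the array, which were left out of the fit across probe sets. The poly-A, ACTB and GAPDH values drew attention because the mean with ANRIL siRNA exceeded the highest control value. The poly-A spike-in controls averaged 7.44 ± 0.46 (SD, n = 3) with ANRIL siRNA, at 7.56, 7.82 and 6.93 on the 3 arrays, and 7.01 ± 0.14 with control siRNA, a difference of 0.43 on the log2 scale (two-sided exact permutation p = 0.3). The difference between 3' and 5' signal of ACTB was higher with ANRIL siRNA by 0.17 (exact permutation p = 0.2), and that of GAPDH by 0.06 (0.06 ± 0.03 against 0.00 ± 0.01, exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The hybridisation controls differed by 0.04 (exact permutation p = 0.7). No explanation of these differences was tested.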

How the results depend on the processing

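Cyclic loess, the intensity trend without the robust option and their combinations were tests chosen only after the results had been seen. Across the settings, list results kept their direction and their side of the threshold 312 times, stopped passing in the same direction 64 times, newly passed 19 times and turned direction 27 times. Among those that turned, oxidative phosphorylation also lost its call after repeated quantile normalization and after cyclic loess. The lists of endothelial identity and p53 targets each stayed lower and past the threshold under 15 of 17 settings, all except the estimated correlation and fry, and S phase did not pass under any of 17. The named genes, none of which passed in the deposited values, kept their direction without passing 1583 times, passed 147 times and turned 23 times. Except where a setting changes the threshold, the number of arrays or the genes tested, the cause was not tested.

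At an unadjusted p under 0.05 there were 4891 higher and 3355 lower probe sets and 1944 higher and 1613 lower genes, and with a 1.5-fold difference as well 2 and 12 probe sets and 1 and 3 genes. At an adjusted p under 0.10 there were 0 of each. With array weights, lists turning direction in the test had an adjusted p of 0.876 (NRF2). With the intensity-trended robust prior, there were 29 higher and 315 lower probe sets and 115 higher and 426 lower genes. LYVE1 passed at −0.43 (rank 1, adjusted p = 0.00598) and −0.559 (rank 2, adjusted p = 0.00282). Calls of lists with an unchanged direction ended at adjusted p-values of 0.0602 (Polycomb), and newly passing lists had 0.032 (lymphatic endothelial). After repeated quantile normalization, there were 2 higher and 4 lower gene lists. The log2 difference turned to −0.055 (CLIP1 rank 3), 0.038 (EZR rank 1) and 0.003 (MTAP). Lists no longer passing in the same direction had adjusted p-values of 0.347 (angiogenesis, leukocyte), 0.144 (adhesion), 0.817 (Polycomb), 0.623 (hypoxia), 0.0768 (matrix) and 0.128 (RNA interference, the follow-up genes), and newly passing lists had 0.0222 (lymphatic endothelial) and 0.000252 (unfolded protein response, cholesterol), or with an estimated correlation 0.276 (lymphatic endothelial and unfolded protein response) and 0.371 (cholesterol). Lists turning direction in the test had adjusted p-values of 0.572 (mitosis), 0.861 (oxidative phosphorylation, which no longer passed), 0.738 (TGF-beta) and 0.347 (fibroblast). With arrays centred on their medians, there were 4 lower probe sets and 1 higher and 31 lower genes. The log2 difference turned to −0.05 (CLIP1 rank 3). LYVE1 passed at −0.61 (rank 2, adjusted p = 0.0476). A list newly passed at an adjusted p of 0.0435 (lymphatic endothelial). The direction of the list test turned at adjusted p-values of 0.977 (NRF2). Above the median signal only, there were 1 lower probe set, 55 higher and 254 lower genes and 2 higher and 4 lower gene lists. Lists no longer passing in the same direction had adjusted p-values of 0.347 (angiogenesis), 0.107 (adhesion, matrix, the follow-up genes), 0.794 (Polycomb), 0.461 (hypoxia), 0.402 (oxidative phosphorylation) and 0.138 (RNA interference), and newly passing lists had 0.0217 (lymphatic endothelial), 0.0104 (unfolded protein response) and 0.00981 (cholesterol). Lists turning direction in the test had adjusted p-values of 0.896 (NF-kB), 0.794 (TGF-beta) and 0.461 (smooth muscle). With the mean of all probe sets per gene, the log2 difference turned to −0.018 (SETMAR), 0.041 (GCLC), 0.002 (SREBF2) and 0.045 (DICER1). Calls of lists with an unchanged direction ended at adjusted p-values of 0.0887 (RNA interference), and newly passing lists had 0.0345 (9p21 neighbours). The direction of the list test turned at adjusted p-values of 0.819 (unfolded protein response) and 0.826 (NRF2). Without probe sets ending in _s_at or _x_at, there were 0 higher gene lists. The log2 difference turned to 0.095 (RGCC), 0.13 (HES1), 0.127 (CCNB1), 0.007 (RBBP4), 0.034 (GCLC), −0.123 (IDI1), 0.03 (COX5A), 0.114 (ATP5PB), 0.179 (TAGLN), −0.029 (SMAD6), 0.082 (TGFB1), 0.177 (COL3A1), −0.122 (MS4A1), −0.055 (ESRP1) and 0.174 (EZR). Lists no longer passing in the same direction had adjusted p-values of 0.257 (Polycomb) and 0.206 (oxidative phosphorylation, leukocyte), and newly passing lists had 0.0386 (9p21 neighbours). Lists turning direction in the test had adjusted p-values of 0.885 (NF-kB), 0.549 (unfolded protein response), 0.869 (cholesterol) and 0.945 (TGF-beta). Camera with an estimated correlation was run on the deposited values, after repeated quantile normalization and after cyclic loess. It was not run under the other settings, so new list calls there were not tested in that way. With camera and an estimated correlation in the deposited values, there were 0 higher and 0 lower gene lists. Calls of lists with an unchanged direction ended at adjusted p-values of 0.466 (endothelial identity, angiogenesis, adhesion, p53 targets, matrix, RNA interference, leukocyte, the follow-up genes), 0.516 (interferon), 0.601 (Polycomb) and 0.603 (hypoxia, oxidative phosphorylation). With fry, there were 0 higher and 1 lower gene list. Lists no longer passing in the same direction had adjusted p-values of 0.0591 (endothelial identity), 0.0964 (angiogenesis, adhesion, the follow-up genes), 0.236 (interferon), 0.087 (p53 targets), 0.176 (Polycomb, hypoxia, leukocyte), 0.263 (oxidative phosphorylation), 0.132 (matrix) and 0.146 (RNA interference), and newly passing lists had 0.0276 (lymphatic endothelial). After cyclic loess, there were 3 higher and 4 lower gene lists. The log2 difference turned to −0.062 (CLIP1 rank 3) and 0.029 (EZR rank 1). Calls of lists with an unchanged direction ended at adjusted p-values of 0.323 (angiogenesis, matrix), 0.384 (adhesion), 0.721 (Polycomb), 0.776 (hypoxia), 0.119 (RNA interference), 0.36 (leukocyte) and 0.132 (the follow-up genes), and newly passing lists had 0.0261 (lymphatic endothelial), 0.000142 (unfolded protein response), 0.0161 (NRF2) and 0.000437 (cholesterol), or with an estimated correlation 0.305, 0.122, 0.432 and 0.395 in that order. The direction of the list test turned at adjusted p-values of 0.618 (mitosis), 0.694 (oxidative phosphorylation, which no longer passed), 0.503 (TGF-beta) and 0.36 (fibroblast). With an intensity trend and no robust option, there were 13 higher and 226 lower probe sets and 107 higher and 415 lower genes. LYVE1 passed at −0.43 (rank 1, adjusted p = 0.00941) and −0.559 (rank 2, adjusted p = 0.00597). After cyclic loess with the trended robust prior, there were 20 higher and 58 lower probe sets and 59 higher and 75 lower genes. The log2 difference turned to −0.062 (CLIP1 rank 3) and 0.029 (EZR rank 1). LYVE1 passed at −0.353 (rank 1, adjusted p = 0.0264) and −0.509 (rank 2, adjusted p = 0.00858).

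With each array left out in turn, adjusted p-values ran from 0.434 to 0.977 for unfolded protein response, 0.453 to 0.976 for NRF2, 0.0064 to 0.225 for leukocyte, 0.61 to 0.977 for epithelial, 0.0109 to 0.0961 for the follow-up genes, 0.0314 to 0.205 for lymphatic endothelial, 0.0178 to 0.133 for Polycomb, 0.497 to 0.976 for fibroblast, 0.0375 to 0.211 for flow-responsive genes and 1.02e-05 to 0.123 for interferon. The number of lists higher ran from 0 to 1, with 0 without control replicate 1 or ANRIL siRNA replicate 3. The log2 difference ran from −0.081 to 0.048 for CLIP1 rank 3, −0.086 to 0.047 for CLIP1 rank 6, −0.159 to 0.024 for ANRIL and −0.004 to 0.175 for CLIP1 rank 4. Limits of signal apply to ANRIL, which lay near the floor of the array, and to the dim probe sets of CLIP1, of which rank 3 lay at 0.00 in the deposited values.

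The labels do not say whether a shared replicate number pairs the samples, and the values do not decide it. Deviations from the group means correlated over probe sets at 0.061, 0.139 and −0.040 for arrays of replicates 1, 2 and 3. Control replicate 1 correlated best with ANRIL siRNA replicate 3 (0.139), and probe sets are not independent replicates. With the replicate block 0 probe sets and 0 genes passed and 12 lists were lower and 1 higher, the list of 9p21 neighbours newly passing (adjusted p = 0.0382). No other call of a list changed.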

Other observations

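Chosen only after results had been seen were cyclic loess, the use of other-cell lists to weigh the share of endothelial cells, the tests on EZR, CLIP1 and control replicate 1, the splits for counts of probe sets and the splits with the study's own list left out.

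Genes of the unfolded protein response, of cholesterol synthesis and of the NRF2 response did not move as lists in the deposited values, but their medians lay at percentiles 100, 100 and 99.8 of random lists of like brightness. Unfolded protein response genes had a median of 0.02 (14 of 26 above 0, adjusted p = 0.697), with the glutathione-degrading enzyme gene CHAC1 at 0.18 ± 0.06, the chaperone genes HSPA5 at 0.10 ± 0.06 and HSP90B1 at −0.21 ± 0.11, and PPP1R15A at −0.16 ± 0.06. After cyclic loess 22 of 26 lay above 0 (median 0.09, adjusted p = 0.000142, and 0.122 with an estimated correlation). Cholesterol synthesis genes had a median of 0.03 (10 of 17 above 0, adjusted p = 0.433), with HMGCS1 at 0.11 ± 0.07, PMVK at 0.13 ± 0.08, IDI1 at 0.10 ± 0.07 (−0.12 without _s_at and _x_at probe sets) and SREBF2 at −0.10 ± 0.07 (0.00 as the mean of its probe sets). After cyclic loess 15 of 17 lay above 0 (median 0.11, adjusted p = 0.000437, and 0.395 with an estimated correlation). The NRF2 list had a median of −0.01, a mean of 0.01 and a positive test (adjusted p = 0.908), with HMOX1 at 0.28 ± 0.09, TXNRD1 at 0.11 ± 0.06, GCLC at −0.12 ± 0.06 (0.03 without _s_at and _x_at probe sets and 0.04 as the mean of its probe sets) and AKR1C1 at 0.12 ± 0.09. After cyclic loess 15 of 18 lay above 0 (median 0.06, adjusted p = 0.0161, and 0.432 with an estimated correlation), but it did not pass after repeated quantile normalization (adjusted p = 0.0768).

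The endothelial identity list was lower by a mean of 0.173, and the highest of the other splits of the 6 arrays gave 0.106. Only 1 of the 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05. Camera with the preset correlation also called this list in mixed splits, at adjusted p-values of 0.021, 0.000257, 0.02, 0.0179 and 0.00965. In the remaining mixed splits the list was not called (0.772, 0.684, 0.1 and 0.121). A camera call of this list alone therefore does not set the real grouping apart. After cyclic loess the list's median lay at percentile 0 of 10000 expression-matched random lists, though it shrank from −0.17 to −0.10. An intensity-dependent difference between arrays is therefore argued against as the whole cause of the shift on these arrays. The random lists lack the correlation between endothelial genes, so the percentile does not weigh chance. By camera with an estimated correlation the adjusted p after cyclic loess was 0.122. A lower share of endothelial cells may contribute and stays open. The medians of the 4 lists of other cells after cyclic loess were −0.051 ± 0.05 (SE, epithelial), −0.043 ± 0.05 (fibroblast), 0.028 ± 0.037 (smooth muscle) and 0.077 ± 0.045 (leukocyte). Unlike the other SEs given here, these come from the spread between the 9 to 12 members of a list, taken as independent. They leave out the spread between arrays, so they cannot decide the question. An effect of the ANRIL siRNA is a hypothesis that also stays open, as do off-target effects of the siRNA, neither of which was tested.

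At the EZR probe set of rank 4 and the CLIP1 probe set of rank 5 in mean signal the differences were −0.59 and −0.58, and −0.31 and −0.21 without control replicate 1. That array was singled out because it was seen to be high there, so the smaller differences do not decide whether it is the cause, which stays open. It exceeded both other controls by 1.5-fold at 121 probe sets, among them 6 of the 12 of MALAT1, a gene named here after its values were seen, against at most 12 probe sets for any other array within its group. At the brightest probe sets the 95% intervals were −0.24 to 0.13 for EZR and −0.30 to 0.04 for CLIP1. These values argue against a fall of the whole transcript by as much as −0.59 or −0.58. A smaller equal fall cannot be told apart from a change of these probe sets alone. The change of the difference from the brightest probe set was −0.54 for EZR (95% interval −1.59 to 0.51) and −0.45 for CLIP1 (−1.41 to 0.51), each with an exact permutation p of 0.3. A biological difference at these probe sets stays open and was not tested further.

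With the intensity-trended robust prior 344 probe sets passed, against at most 1 in any other split of the 6 arrays, and 1 of the 10 splits, the real one, was as large. The count of the real split moved when an array was left out. It ran from 0 higher and 4 lower without control replicate 2 to 170 higher and 715 lower without ANRIL siRNA replicate 2. After cyclic loess 78 probe sets passed with the trended robust prior, 63 of them among the 344, and 0 passed with the constant prior. The count after cyclic loess was not taken in the other splits or with an array left out. It therefore does not decide whether an intensity-dependent difference between arrays is the whole cause. Such a difference may account for part of the 344. The counts at an unadjusted p under 0.05 were 8246 for the real split and at most 4775 for the others, so 1 of 10 was as large, and of the gene lists 12 passed against at most 10, again 1 of 10, or 11 against at most 9 with the list chosen by the study on these samples left out. At an adjusted p under 0.05 with the constant prior all 10 splits gave 0 probe sets and 0 genes. In each case 10 splits are too few for a share under 0.05.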
